A study of Mus musculus with 8 samples.

How the data were processed

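The data are chromatin immunoprecipitation sequencing with a spike-in reference (ChIP-Rx) from C3H10T1/2 cells, a mouse embryo line of mesenchymal progenitor cells. The cells stably expressed FLAG-HA-tagged histone H3.3, either wild type (WT) or with lysine 36 replaced by methionine (K36M), and were used at passages 10 to 15. Chromatin was cut to mononucleosomes with micrococcal nuclease. Soluble chromatin of Drosophila S2 cells equal to 5% of the mouse chromatin was added before precipitation with antibodies against H3K36me3, H3K36me2 or H3K27me3. The series has 8 samples, 1 per group: 6 ChIP libraries (3 marks in 2 genotypes) and 2 input libraries. The input libraries were not analysed here.

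The deposited values are a signal, the reads in each peak scaled to the Drosophila spike-in by the authors, per the file headers. Each mark has 1 table of peaks with 1 value per genotype, so both libraries were measured over the same regions. Bowtie 1.0.0 and the builds mm9 and dm6 are named in the submitters' processing notes. The numbers of rows, 4999 and 999 in 2 of the tables, leave open that the lists were ended at a fixed length. The peak caller, its settings, the library or libraries in which peaks were called and the formula of the scaling factor are not given in the sources used here. All starts are multiples of the same window size and all ends fall on its last base, as in windows counted from 0. Coordinates are printed as deposited, and adding 1 to both ends would give the position in a browser that counts from 1. The mouse build is taken as mm9. The only gene table used here belongs to another build, so no peak was given a gene name and the gene lists fixed for this work were not tested.

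In each of the 6 columns, 1 step was found as the greatest common divisor of the values in hundredths. All values are whole multiples of it by construction, so only its size is informative. The step was 0.39 for H3K36me3 in WT and 0.22 in K36M. It was 1.08 and 0.52 for H3K36me2, and 0.18 and 0.26 for H3K27me3. As every step was far larger than 1 hundredth, the values were read as whole reads multiplied by 1 factor per library. Steps given to 2 decimals would be uncertain by 0.005 if they were rounded, which is 0.463% to 2.78% of a step. Total library sizes and numbers of Drosophila reads were not used here.

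For each peak the K36M value was divided by the WT value, with no pseudocount, since no value was 0. Summaries are the median log2 ratio, the ratio of total signal over all peaks of a mark, and the number of peaks that differed at least 2-fold. With 1 library per genotype and mark, no test between genotypes was made and no p-value is given. All differences lack a replicate check. Ratios of single peaks have exact Clopper-Pearson 95% intervals computed from the reads of both libraries, which cover counting error only. Medians over peaks have 95% binomial intervals from the ranks of the peaks. These would give the precision of the median if peaks were independent draws. They do not show the spread of the peaks, and peaks are not replicates. Peak sets were compared by an overlap of at least 1 bp, beside 100 rotations of the peaks within each chromosome's range. A subset's median was placed among 10000 random sets of the same size matched on mean signal in 10 bins. Named regions were chosen, before the data were examined, among each mark's peaks with a mean of both genotypes at or above the median: the 8 lowest ratios, the 8 highest ratios and the 4 highest WT values. The rules for peaks in gene lists could not be applied.

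Alternatives were a pseudocount at the 5th percentile of the values, only peaks with a mean at or above the median, autosomes only, a 1.5-fold threshold, both libraries scaled to the same total, other overlap rules and other distances. The range allowed by rounded factors was added after the data were seen, as were the alternatives of the comparisons inside overlapping peaks. The calculations were tested on simulated counts for the real peaks, in which 200 peaks per mark were changed by 1.5 on the log2 scale. A changed peak counted as recovered if it lay at least 2-fold from the simulated median, in the direction of its change. By this rule 100% were recovered for H3K36me3 and for H3K27me3, and 99.5% for H3K36me2. The simulation held counting error only, so it does not cover error between libraries. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.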

Results

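The study asked how the H3.3 K36M mutation changes the methylation of histone H3 at lysines 36 and 27 across the genome. The 3 marks were measured in C3H10T1/2 cells that expressed WT or K36M H3.3, with 1 library per mark and genotype. H3K36me3 is deposited by SETD2 over the bodies of transcribed genes. H3K36me2 is deposited largely by the NSD enzymes, over genes and between them. H3K27me3 is deposited by Polycomb repressive complex 2 over silenced regions. The H3K36me3 table listed 4999 peaks over 234 Mb, with a median length of 35.8 kb. The H3K36me2 table held 1691 peaks over 43.8 Mb with a median length of 14.4 kb, and the table for H3K27me3 held 999 peaks over 33.7 Mb with a median length of 24.2 kb. Whether the tables list all called peaks or were ended at a fixed number of rows is not known, so counts, covered lengths and shares describe the listed peaks. Counted in steps of each library's factor, reads inside peaks numbered 11294217 in WT and 6095048 in K36M for H3K36me3, 1770960 and 915902 for H3K36me2, and 1703298 and 1124047 for H3K27me3. The median peak held 306 to 1715 reads per library, so counting error was small against the differences between most peaks. It does not stand for the error between cultures, which was not measured.

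On the spike-in scale, H3K36me3 was lower in the K36M library in all 4999 peaks. Total signal over the peaks was 4404745 spike-in normalized reads in WT and 1340911 in K36M, which is 30.4% of the WT level or a 3.28-fold difference. The median peak had a log2 ratio of −1.71 (95% interval over peaks −1.72 to −1.71), and 4926 peaks (98.5%) were at least 2-fold lower. The quartiles over peaks were −1.85 and −1.55, so most domains were lower by a similar factor. Long peaks were slightly lower than short ones: the fifth of shortest peaks had a median of −1.63 and the fifth of longest peaks −1.76.

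The 4 H3K36me3 domains with the highest WT values were 2.91-fold to 3.90-fold lower. The domain with the highest WT value, on chromosome 15 from 63897800 to 64221199, had 8680 normalized reads in WT and 2983 in K36M, 2.91-fold lower. Domains on chromosome 11 from 86299200 to 86572599 and on chromosome 4 from 57580600 to 57911599 were 3.49-fold and 3.90-fold lower. The 8 regions with the lowest ratios were 6.37-fold to 7.94-fold lower. The first of them was a 36.4 kb region on chromosome 15, from 54073200 to 54109599, with 1002 normalized reads in WT and 126 in K36M, a ratio of 0.126 (counting interval 0.115 to 0.138). A 197 kb domain on chromosome 8, from 46720800 to 46917799, had a ratio of 0.134 (0.129 to 0.139). Of the 8 regions with the highest ratios, 5 lay on chromosome 13. The 8 were between 1.82-fold and 1.99-fold lower, the least affected being on chromosome 6 from 149259400 to 149289399 with a ratio of 0.550 (0.512 to 0.591).

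H3K36me2 was also lower in the K36M library in all 1691 peaks on the spike-in scale, and by more than H3K36me3. The marks have separate antibodies, peak sets and spike-in factors, so the error of this ranking was not measured. Total signal was 1912637 normalized reads in WT and 476269 in K36M, 24.9% of the WT level or 4.02-fold lower. The median log2 ratio was −2.07 (interval over peaks −2.09 to −2.05). At least 2-fold lower values were found in 1641 peaks (97.0%), and 998 peaks (59.0%) were at least 4-fold lower, against 498 (9.96%) of the H3K36me3 peaks. The change varied more between H3K36me2 peaks than between H3K36me3 peaks, with SDs of 0.40 and 0.27 on the log2 scale. Counting error alone would give 0.13 and 0.08, and variation between cultures and precipitations is not separated from the rest.

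The 4 H3K36me2 domains with the highest WT values were 4.60-fold to 5.15-fold lower. A block of 3 neighbouring domains on chromosome 11, from 111429600 to 112539999, was 4.91-fold to 5.15-fold lower. The domain with the highest WT value, on chromosome 10 from 83255200 to 83617799, had 24045 normalized reads in WT and 5226 in K36M, 4.60-fold lower. Of the 8 regions with the lowest ratios, 7 lay on chromosome 15, and the 8 were 6.29-fold to 7.05-fold lower. One of them, a 165 kb domain on chromosome 15 from 61122600 to 61287399, had 7963 normalized reads in WT and 1231 in K36M, a ratio of 0.155 (0.148 to 0.162). The 8 regions with the highest ratios had ratios of 0.594 to 0.749, and 7 of them overlapped an H3K36me3 peak. The region on chromosome 1 from 33835400 to 33877199 had the highest ratio, with 2668 normalized reads in WT and 1998 in K36M. Regions on chromosome 8 near the positions 19781000 and 19938200, and on chromosome 4 near 145019600 and 146891600, were also in this set.

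The sizes of both differences, and the direction in single peaks, rest on the spike-in factors. With both libraries of a mark scaled to the same total, the median log2 ratio would be 0.0030 for H3K36me3 and −0.062 for H3K36me2, by construction of that scaling. In reads without the factors, the K36M library held 0.540 times as many reads inside H3K36me3 peaks as the WT library and 0.517 times as many inside H3K36me2 peaks. If the factors were rounded to 2 decimals, the fold differences lie between 3.17 and 3.40 for H3K36me3 and between 3.96 and 4.07 for H3K36me2, before any error between cultures.

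**Figure D1:**
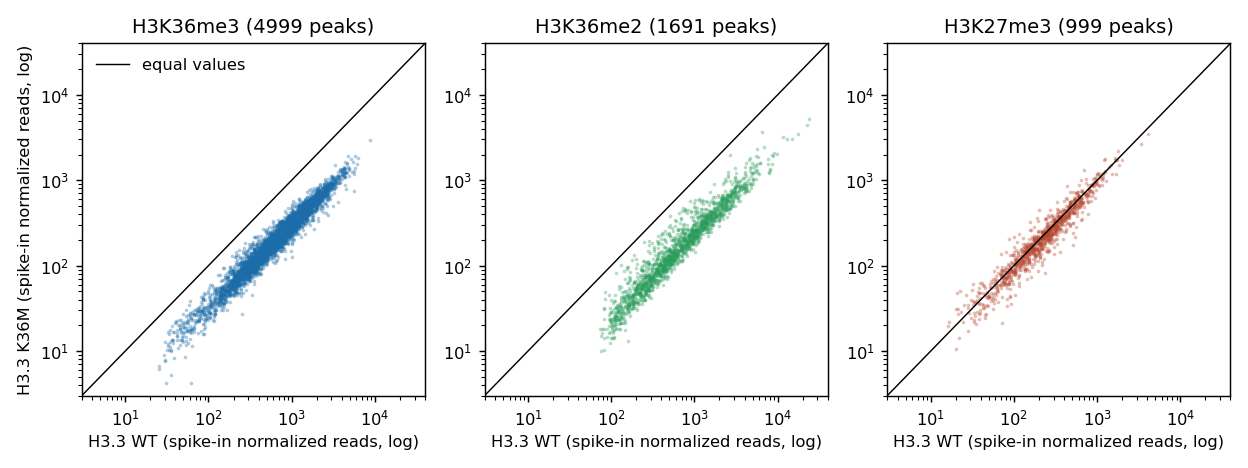
Spike-in normalized reads per peak in WT (x axis) and K36M (y axis), both on log scales, for H3K36me3, H3K36me2 and H3K27me3; each point is 1 peak, and the line marks equal values. On this scale, which equal totals would remove, all 4999 H3K36me3 and all 1691 H3K36me2 peaks lie below the line, and the 999 H3K27me3 peaks lie on both sides of it.

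H3K27me3 totals over the listed peaks differed little between the genotypes on the spike-in scale. Signal outside the listed peaks was not measured here, so this says nothing of H3K27me3 in the rest of the genome. Total signal over its peaks was 306594 normalized reads in WT and 292252 in K36M, a ratio of 0.953, and the median log2 ratio was −0.08 (interval over peaks −0.10 to −0.06). Of the 999 peaks, 624 were lower and 375 were higher in K36M. The range of ratios that rounded factors allow is 0.910 to 0.999, so a difference of this size is close to the precision of the scaling itself. In reads without the factors, the K36M library held 0.660 times as many reads in these peaks as WT.

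Behind the nearly equal totals, H3K27me3 values were lower in some domains and higher in others. The SD of the log2 ratios was 0.36, and counting error alone would give 0.08. The variation between cultures and precipitations, which also enters this spread, was not measured. In K36M, 17 peaks were at least 2-fold lower and 7 at least 2-fold higher, and at 1.5-fold these counts were 81 and 34. They were 4 and 1 with a pseudocount, and 5 and 2 among peaks with a mean at or above the median, both at 2-fold. Among the 8 regions with the lowest ratios, 6 lay on chromosome 15 between 39933200 and 53859799. The first, from 40944200 to 40989599, had 506 normalized reads in WT and 174 in K36M, a ratio of 0.344 (0.316 to 0.375). Other regions of this chromosome, from 41166200 to 41227199 and from 53813600 to 53859799, had ratios of 0.400 and 0.410. The medians of H3K36me2 and H3K36me3 peaks from 39 to 63 Mb of this chromosome were also below those of all their peaks, as the plot along chromosome 15 shows. These bounds were drawn around low values after the values were seen, so the lower medians add no support. Elsewhere, a region on chromosome 16 from 26503200 to 26560599 had a ratio of 0.469 (0.435 to 0.505).

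The highest H3K27me3 ratio among the named regions was on chromosome 5, from 14946800 to 14964199, with 200 normalized reads in WT and 447 in K36M, a ratio of 2.23 (2.07 to 2.41). A region on chromosome 16 from 3232600 to 3255999 had a ratio of 2.07 (1.90 to 2.26). A 31.8 kb domain on chromosome 8, from 19853800 to 19885599, had 429 and 858 normalized reads, and a 77.6 kb domain on chromosome 1, from 33870800 to 33948399, had 692 and 1306. Of the 8 regions with the highest H3K27me3 ratios, 4 overlapped an H3K36me2 peak. The 4 domains with the highest WT values had ratios of 0.781 to 0.881. The largest, on chromosome 15 from 102725000 to 102978399, had 4091 and 3453 normalized reads, a ratio of 0.844 (0.826 to 0.862). The next, on chromosome 11 from 96006400 to 96248199, had a ratio of 0.781 (0.762 to 0.800). Over all peaks, the fifth with the lowest WT density had a median log2 ratio of 0.03 (−0.04 to 0.09) and the fifth with the highest −0.16 (−0.25 to −0.11). The WT value is also the denominator of the ratio, so choosing or splitting peaks by it favours lower ratios at high WT values, and part of this difference is built into the split.

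**Figure D2:**
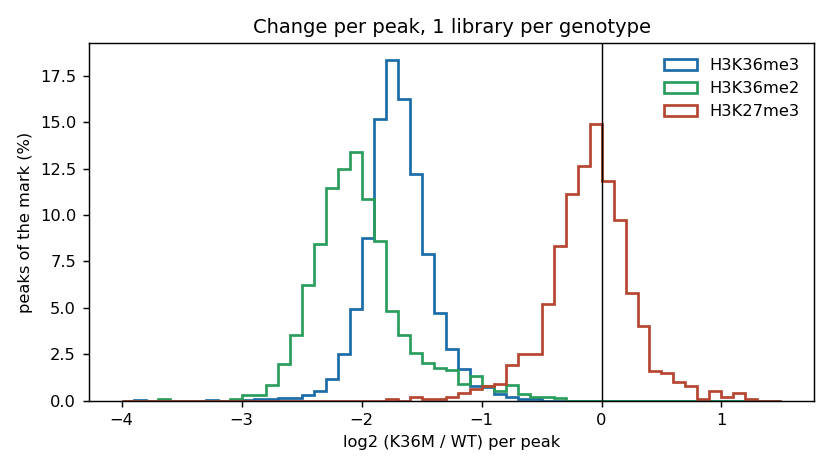
Distribution of the log2 ratio of K36M to WT per peak (x axis), as the percentage of each mark's peaks in bins of equal width (y axis); the vertical line marks no difference. The medians are −1.71 for H3K36me3, −2.07 for H3K36me2 and −0.08 for H3K27me3.

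The ratios also differed between chromosomes. On chromosome 13 the median H3K36me3 log2 ratio was −1.33, which is 0.39 above the median of all H3K36me3 peaks (interval of the deviation 0.33 to 0.41, 185 peaks). H3K36me2 was 0.14 above its own median there (0.09 to 0.24, 50 peaks), and H3K27me3 0.26 above (0.03 to 0.39, 12 peaks). On chromosome 18, H3K36me3 was 0.31 above its median (0.26 to 0.39, 118 peaks). On chromosome X, H3K27me3 was 0.58 above its median (0.40 to 0.70), with 17 of 19 peaks higher in K36M, and H3K36me3 was 0.30 above (0.23 to 0.34, 67 peaks). On chromosome 15 all 3 marks were below their medians, H3K36me3 by a deviation of −0.17, H3K36me2 by −0.09 and H3K27me3 by −0.14. Outside the part from 39 to 63 Mb, chosen after the values were seen, the deviation was −0.15 for H3K36me3 and −0.10 for H3K27me3, but 0.02 for H3K36me2 (−0.03 to 0.10, 191 peaks). On chromosome 17 all 3 marks were above their medians, by 0.07, 0.19 and 0.12. On chromosome 11 the marks differed in sign: H3K36me3 deviated by −0.11 (−0.13 to −0.09, 408 peaks) and H3K27me3 by −0.06 (−0.11 to −0.02, 95 peaks), but H3K36me2 by 0.17 (0.08 to 0.28, 136 peaks).

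**Figure D3:**
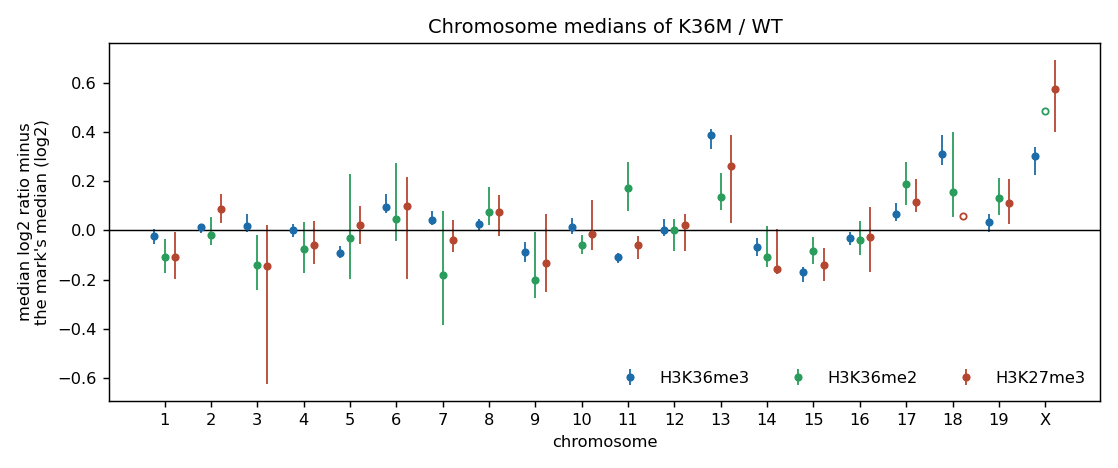
Median log2 ratio of K36M to WT of the peaks on each chromosome minus the median of all peaks of the mark (y axis, log2), by chromosome (x axis); bars are 95% binomial intervals of the median over peaks, and open circles mark chromosomes with too few peaks for an interval. The intervals of all 3 marks lie above 0 on chromosomes 13 and 17 and below 0 on chromosome 15. The marks differ in sign on chromosomes 2, 3, 4, 5, 7, 10 and 11. Only on chromosome 11 do intervals lie wholly on both sides of 0, with H3K36me2 above and the other marks below. The remaining chromosomes have 1 sign in all marks, with an interval that reaches 0 or is missing.

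The listed H3K27me3 peaks overlapped listed H3K36 methylation peaks less often than their rotations did, which says nothing of peaks that the tables leave out. In all, 56 of the 999 H3K27me3 peaks (5.61%) overlapped a peak of H3K36me2 or H3K36me3, against a median of 213.5 (182 to 251) in 100 rotations of the peaks along their chromosomes. Against H3K36me3 the counts were 41 overlapping peaks and 144 to 205 in the rotations. Against H3K36me2 the gap was smaller, with 38 overlapping peaks and a median of 59 (34 to 88) in the rotations, of which 1 was at or below the observed count. H3K36me2 and H3K36me3 overlapped more than rotations gave: 336 of 1691 H3K36me2 peaks (19.9%) met an H3K36me3 peak, against 222 to 325.

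H3K27me3 peaks near H3K36 methylated domains differed from the others by small amounts, with no common direction over the distances used. The 528 peaks within 50 kb of an H3K36me2 or H3K36me3 peak had a median log2 ratio of −0.09, and the 471 others −0.08. The near peaks' median was at percentile 18.7 of random sets of equal size and signal. At 10 kb the difference was −0.04, with the 237 near peaks at percentile 4.45, and at 200 kb it was 0.07, with the 877 near peaks at percentile 83.3.

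H3K27me3 peaks that overlapped an H3K36 methylation peak by at least 1 bp had higher ratios than the others. The ratios were taken over whole peaks, and the shared stretches were not measured. The 38 H3K27me3 peaks that overlapped H3K36me2 had a median log2 ratio of 0.48 (0.10 to 0.66), and 28 of them were higher in K36M. The other 961 had a median of −0.09, and 36.1% of them were higher. The 38 peaks' median was above all 10000 random sets matched on signal, whose central 95% ran from −0.16 to 0.03. The 40 H3K36me2 peaks in these overlaps were 2.40-fold lower at the median, against 4.22-fold for the other H3K36me2 peaks, so their loss was smaller than that of the rest. The 41 H3K27me3 peaks that overlapped H3K36me3 had a median log2 ratio of 0.27 (0.15 to 0.66), and the 46 H3K36me3 peaks that overlapped H3K27me3 had −1.23 (−1.45 to −1.09) against −1.72 for the others. Both medians were above all matched random sets. The chromosome 1 region from 33870800 to 33948399 is an example, with H3K27me3 1.89 times its WT value and the overlapping H3K36me2 peak 1.33-fold lower. That H3K36me2 peak runs from 33835400 to 33877199, so the peaks share only part of their lengths.

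H3K36me2 was also lower by less in peaks that overlapped an H3K36me3 peak by at least 1 bp. The 336 H3K36me2 peaks that overlapped an H3K36me3 peak had a median log2 ratio of −1.63 (−1.71 to −1.55), a 3.10-fold loss. The other 1355 had a median of −2.13 (−2.15 to −2.11), a 4.37-fold loss. The median of the overlapping peaks was above all 10000 matched random sets, whose central 95% ran from −2.10 to −2.03. In K36M the overlapping peaks had a median of 14.3 normalized reads per kb and the others 9.85, from 45.0 and 42.0 in WT. H3K36me3 differed little in the same overlaps: the median log2 ratio was −1.74 (−1.77 to −1.70) in its 326 peaks that overlapped H3K36me2 and −1.71 (−1.72 to −1.70) in the other 4673, with the overlapping peaks at percentile 3.19 of matched random sets.

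**Figure D4:**
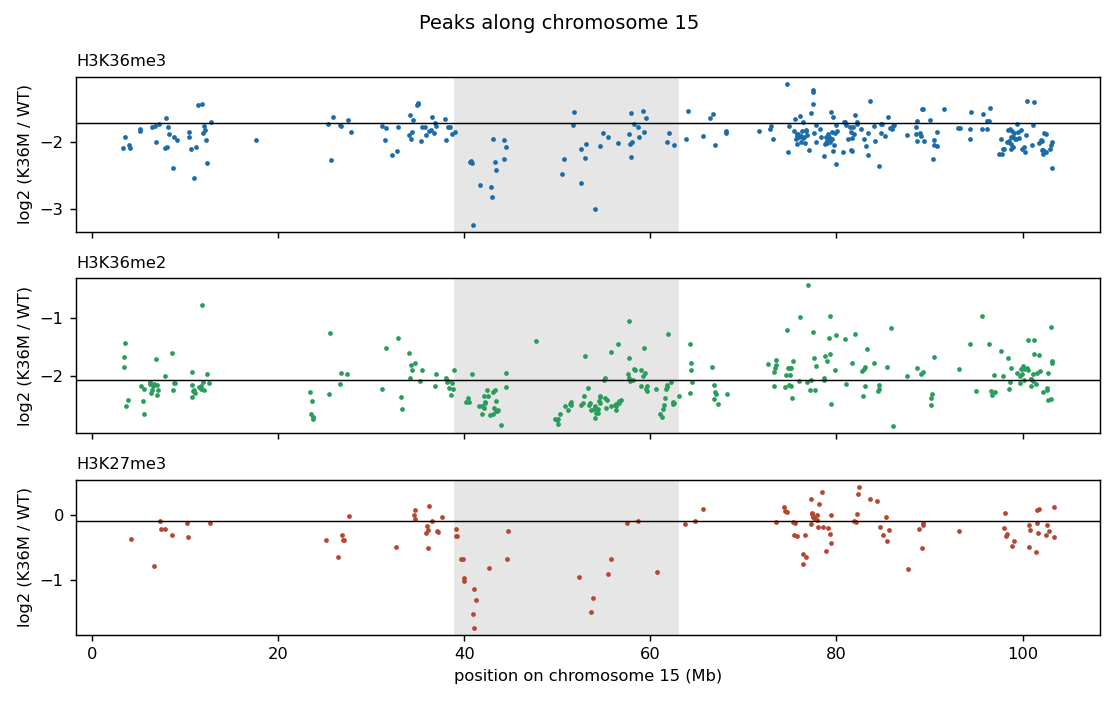
Log2 ratio of K36M to WT (y axis) of each peak along chromosome 15 (x axis, position in Mb), with 1 panel per mark; the line is the median of all peaks of the mark and the shaded part runs from 39 to 63 Mb, bounds chosen after the values were seen. Within the shaded part the medians are lower than the mark's median by deviations of −0.32 for H3K36me3 (40 peaks), −0.38 for H3K36me2 (100 peaks) and −0.76 for H3K27me3 (22 peaks).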

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

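Every size depends on the spike-in factors. With both libraries of a mark scaled to the same total, the median log2 ratios became 0.0030 for H3K36me3, −0.062 for H3K36me2 and −0.015 for H3K27me3, because that scaling removes the global difference by construction. The peaks at least 2-fold lower were then 10 for H3K36me3 and 2 for H3K36me2, and those at least 2-fold higher 8 and 50. Rounded factors, a range added after the data were seen, allow total ratios of 0.294 to 0.315 for H3K36me3, 0.245 to 0.253 for H3K36me2 and 0.910 to 0.999 for H3K27me3. A pseudocount at the 5th percentile moved the medians to −1.45 for H3K36me3 and −1.76 for H3K36me2, and the H3K27me3 counts to 4 lower and 1 higher. With only peaks of a mean at or above the median, the H3K36me3 median was −1.73. The counts at least 2-fold lower were then, with fewer peaks tested, 2492 for H3K36me3, 822 for H3K36me2 and 5 for H3K27me3, and 2 H3K27me3 peaks were at least 2-fold higher. At 1.5-fold, 81 H3K27me3 peaks were lower and 34 higher. Without the 1% of peaks of highest signal the total ratio was 0.305 for H3K36me3 and 0.252 for H3K36me2. On autosomes it was 0.304 for H3K36me3 and 0.945 for H3K27me3. Requiring at least 50% of an H3K27me3 peak to be covered left 28 overlaps of the 56. The difference between H3K27me3 peaks near and far from H3K36 methylation was −0.039 at 10 kb and reversed to 0.070 at 200 kb, and the cause was not tested. The smaller H3K36me2 loss in peaks that overlap H3K36me3 was a difference of 0.39 without the densest 10% of peaks. It was 0.75 where H3K36me3 covered at least 50% of the peak. Both settings were added after the data were seen. The other 29 values stayed within the interval of the value reported, or within 1.5 times a count. The gene lists were not run, and no replicate could be left out. The median peak held 306 reads or more in each library, and the error between cultures was not measured.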

Other observations

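The tests of chromosomes 11 and 13, of the chromosome 15 segment, of H3K36me2 loss in the overlaps with H3K27me3, of WT density in both kinds of overlap, of the H3K27me3 pairs left without dense ones, of the pairs with H3K36me3 and of the antibody, in all overlaps and in those of at least 50%, were chosen after the results, or part of them, were seen. The tests on windows were fixed before the window values were seen but after the chromosome medians were. All were made on the data in which the patterns were found, with 1 library per genotype.

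The listed H3K36me2 domains were unevenly spread over the genome. Chromosome 15 held 17.2% of the H3K36me2 peaks and 27.6% of the WT H3K36me2 signal, whereas it held 5.58% of the H3K36me3 peaks and 7.45% of their signal. It also held 11.9% of the H3K27me3 peaks. Chromosome 18 held 0.887% of the H3K36me2 peaks and chromosome X held 2 peaks, while H3K36me3 had 118 and 67 peaks there. WT H3K36me3 density was highest on chromosome 15, at 21.9 normalized reads per kb of peak, and was 16.7 on chromosome 18 and 16.5 on chromosome X.

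The first pattern is that the marks tended to shift together by region: in windows of 5 Mb, which are not replicates, Spearman's rho between deviations from each mark's median was 0.28 for H3K36me3 and H3K36me2 (Pearson's r 0.50, 196 windows), 0.36 for H3K36me3 and H3K27me3 (0.60, 147 windows) and 0.63 for H3K36me2 and H3K27me3 (0.71, 99 windows). For the pairs with H3K36me3, rho was 0.17 and 0.19 within chromosomes and 0.21 and 0.20 without the 10% of windows most extreme in H3K36me3, near the highest rotations of the full values (0.17 and 0.18), but 0.27 and 0.25 without chromosomes 13, 15, 18 and X, and for H3K36me2 and H3K27me3 it was 0.55 within chromosomes. Chance is argued against for the full values, since 0 rotations of a mark along the genome (100, 100 and 89 rotations) reached them. Overlap of the peaks is argued against as the whole cause, since the lowest rho was 0.29 without peaks that overlap another mark (highest rotation 0.27). A gain of H3K27me3 where most H3K36me2 was lost would by itself give a rho below 0, and 0.63 was found. That value cannot decide on such a gain, since a shift of all marks in a region raises rho, and unlisted regions were not counted. A different DNA copy number or depth of a region in the 2 cell populations may contribute, as every rho was above 0, which it needs (the lowest was 0.275), while the chromosome 15 segment from 39 to 63 Mb, with deviations of −0.32, −0.38 and −0.76 (and −0.13, 0.09 and −0.02 from 57 to 60 Mb), decides nothing, because its bounds were drawn around low values. An equal shift of all marks is argued against on chromosome 13, where the smallest deviation, 0.14 for H3K36me2, had an interval apart from that of H3K36me3 at 0.39. It is also argued against on chromosome 11, where H3K36me2 at 0.17 lay apart from H3K36me3 at −0.11 and H3K27me3 at −0.060. Intervals were also apart on other chromosomes, looked at after the values were seen. On X, H3K36me3 (0.23 to 0.34) lay apart from H3K27me3 (0.40 to 0.70). On the whole of chromosome 15, H3K36me3 (−0.21 to −0.15) lay apart from H3K36me2 (−0.13 to −0.03). All these intervals treat neighbouring peaks as independent, which was not checked. An equal shift is not argued against on chromosome 17, looked at after the values were seen. There the intervals of H3K36me3 (0.04 to 0.11), H3K36me2 (0.10 to 0.28) and H3K27me3 (0.08 to 0.21) overlapped. On chromosome 18 those of H3K36me3 (0.26 to 0.39) and H3K36me2 (0.05 to 0.40) overlapped, and H3K27me3 had too few peaks for an interval. The input libraries, which bear on copy number, were not used here, and an effect of the mutation on all marks of a region stays open and untested.

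The second pattern is the higher H3K27me3 in the 38 peaks that overlap H3K36me2. A local gain in proportion to the loss of H3K36me2 would need a loss at least as large as elsewhere. The overlapping H3K36me2 peaks had a median log2 ratio of −1.26 against −2.08 for the others, and the central 95% of random sets ended at −1.95. This cannot decide, as excess mapped reads in these regions could make the loss look smaller. The ratios also cover whole peaks, and the shared stretches were not measured. Regions with excess mapped reads in every library are a candidate explanation that stays open, and a first test went with it: in 26 of the 38 pairs (68.4%, exact 95% interval 51.3% to 82.5%) the WT density was above the list's median in both marks. Other values go with it too, as 23 of the 38 pairs, with all of the 8 highest and the 6 on chromosome 5, also overlapped H3K36me3, and the H3K27me3 median was 0.61 in these 23 (0.15 to 0.94) and 0.23 in the 15 others (−0.16 to 0.50). A second test, added after the first had come out that way, left the 26 pairs out and did not decide, as the 12 others still differed by 0.58 on the log2 scale but with an interval from −0.15 to 0.94; the densest peaks alone are argued against as the whole cause, as the difference was 0.58 without the densest 10% of H3K27me3 peaks. The difference was 0.48 after each chromosome's median was subtracted, and a gain of H3K27me3 caused by the mutation in these regions stays open and untested.

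The third pattern is the smaller loss of H3K36me2 in peaks that overlap H3K36me3 peaks. A weaker WT signal is argued against, as the overlapping peaks had a WT density of 45.0 normalized reads per kb, above the interval of the others' median (41.7 to 42.4). Density does not show the share of background, and the input libraries were not used, so more background in these peaks stays open. The densest 10% of peaks alone are argued against as the whole cause, as the difference was 0.39 without them. Regions with excess mapped reads can lie below that density, so they stay open as an explanation. An H3K36me2 antibody that also reads H3K36me3 would place the H3K36me2 median between that of other peaks and that of the H3K36me3 partners. Over all overlapping peaks this cannot be told apart from a real retention, as the median lay 0.11 above the partners' with intervals that overlap (−1.71 to −1.55 and −1.77 to −1.70). In the 191 peaks covered over at least 50% of their length, the median of −1.36 (−1.44 to −1.25) lay 0.34 above the partners' −1.70 (−1.75 to −1.62), more than the 0.07 that rounded factors allow. This argues against the antibody as the whole cause only if the partners' ratios hold in the shared stretches. Those ratios were taken over whole H3K36me3 peaks, and the shared stretches were not measured. The 2 marks were compared on separate spike-in factors whose error between libraries was not measured, so a retention of H3K36me2 in H3K36me3 domains of K36M cells stays a hypothesis.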
